A study of Mus musculus with 10 samples.

How the data were processed

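The data are 10 two-colour oligonucleotide arrays of mouse neocortex at E11.5, each holding the rostral and the caudal RNA of a pool of 3 embryos. Per the labels, RNA was extracted with Trizol and the cDNA amplified before labelling, and the 2 arrays of a pool carry the dyes in opposite order. The array type beyond its probe names, the scanner, background correction and any normalization are not given in the sources used here. The series' design text speaks of 3 sets per strain; a C57 set beyond the 2 used is not analysed here.

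The deposited table holds log2 ratios of the 2 channels, a unit read from the values: they are positive and negative, values equal to the log2 of small whole-number ratios recur, and 436 values sit at a shared ceiling of 16.61, the log2 of 1e+05. The deposited ratios were taken to be un-normalized by the authors, since the array medians were -0.16, 0.20, 0.67 and -0.07 for C57 (pool 1, pool 1 with dyes exchanged, pool 2, pool 2 with dyes exchanged) and 0.07, 0.45, 0.19, 0.01, 0.23 and -0.01 for the MF1 pools in the same order. Which channel is the numerator is not stated. Ratios were read as Cy5 over Cy3, which the dye labels and the gradient genes make likely; the columns of a pool had opposite signs for the clear gradient genes, so the authors had not turned them.

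Values at the ceiling were treated as missing, on the untested reading, which no label states, that they stand for a ratio without a denominator, and so were values given as null. The 232 control spots for Gapdh were left out, leaving 21766 probes. Each array was turned to caudal over rostral, and the 2 arrays of a pool, which hold the same RNAs, were averaged to 1 value. A probe was tested when both dye orientations were measured in at least 2 pools of each strain, which 11855 probes met. Arrays were not centred, as fixed before the data were examined. Of the 21766 probes, 16632 carried 1 gene symbol in the platform annotation, 139 several and 4995 none; 15952 symbols were matched by gene identifier to the RefSeq genes of GRCm38.p6, none changed, and the other 680 were kept. No gene was named from a probe with several symbols. The tested probes covered 9214 named genes, 452 of them with more than 1 probe; probes were tested separately. The build behind the probes is not given in the sources used here, so no coordinates are printed.

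The pool values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with a coefficient for each strain. The contrasts were the mean of both strains against 0, each strain against 0, and MF1 minus C57. There were 2.69 prior degrees of freedom, and 3 residual ones for a probe measured in all 5 pools. Probes with a missing pool had fewer. Tests were two-sided, and p values were adjusted by Benjamini-Hochberg over the 11855 probes with a threshold of 0.05. Errors are limma's moderated SE. By exact sign changes of single pools, 5 pools cannot give a two-sided p below 0.0625.

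Gene lists for pathways, cortical cell types, neighbouring tissues, blood, tissue state and known rostral or caudal gradients were written before the data were examined, and 27 with at least 5 tested genes were used. The list test was limma's camera in its pre-ranked form with a preset correlation of 0.01, because camera itself takes no missing values. Camera with an estimated correlation and fry were run on the 8924 probes measured in all 5 pools. Genes were named by a rule also fixed beforehand: since no probe passed, the 5 probes of smallest p in each direction, the member of smallest p of each list, Emx2, Nr2f1, Pax6, Sp8, Fgf8, Fgf17, Fgfr3 and Etv5 where measured, and the 2 probes of smallest p for the strain difference. Other genes named were chosen after their values were seen.

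The procedure was tested on simulated data with the spread between pools, mean dye bias and missing values of these arrays and an assumed noise of SD 0.1. That noise was the same for both arrays of a pool once turned, and the dye bias cancelled in their mean. Independent array noise and leftover dye bias were therefore not simulated. In 11855 simulated probes, 200 were changed for the mean of both strains; none was recovered at a log2 change of 0.5, 2 at a change of 1 and 198 at a change of 2, when 9 unchanged probes were called as well. Lists of 10 probes shifted by 0.5 were recovered in 20 of 20 cases, with independent probes.

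Alternatives covered centring and scaling of the arrays, the probe filter, the handling of the dye exchange, averaging the probes of a gene, the variance model, thresholds, the model and leaving out each pool. Keeping ceiling values, centring combined with other choices and leaving gradient genes out of lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.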

Results

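Gene expression was compared between the rostral and the caudal part of the mouse neocortex at E11.5, when the cortical wall is still mostly proliferating neuroepithelium. Tissue came from an inbred strain, C57, and an outbred stock, MF1, so that differences between the ends of the cortex could be told from differences between strains. A pool held material from 3 embryos, and the rostral and caudal RNA of a pool were amplified, labelled with Cy3 and Cy5 and hybridised together on a 2-colour array. Each pool was hybridised on 2 arrays with the dyes exchanged. The 10 arrays therefore hold 5 pools, 2 of C57 on 4 arrays and 3 of MF1 on 6 arrays. Of 21766 probes, the C57 arrays gave a ratio for 20191 to 20870 and the MF1 arrays for 13723 to 18288. The number of arrays limits the precision. Each pool was taken within a litter, and p-values measure the spread between pools.

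All values are log2 ratios of caudal over rostral RNA, so a positive value means more RNA at the caudal end. That direction is likely but not stated with the values: it takes the deposited ratio as Cy5 over Cy3. It rests on the dye labels and on 14 textbook gradient genes, of which 10 lay on the listed side (exact binomial test, two-sided, p = 0.18). All 5 of these genes with a limma p under 0.05 lay on that side, Etv1, Etv5, Spry1 and Dusp6 rostrally and Nr2f1 caudally (exact binomial test, p = 0.0625). The first 4 are FGF targets and so are not separate evidence. With the opposite reading every sign below would turn together. The median ratio of the 5 pools ranged from -0.18 to 0.36, because the deposited ratios were not centred.

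The first question was which genes differ between the rostral and the caudal neocortex in both strains. The largest caudal ratio among the probes of smallest p was that of Nr2f1, a nuclear receptor known for its caudal gradient in the cortical primordium, at 1.85 ± 0.22 (SE, n = 5 pools), 3.60-fold. A second Nr2f1 probe gave 0.57 ± 0.20, and the mean of both probes was 1.21. Ttr, the thyroid hormone carrier made by the choroid plexus, had a ratio of 1.68 ± 0.19, and Timp1, an inhibitor of matrix metalloproteinases, 1.49 ± 0.19. Timp1 depended on the dye order, with 2.35 on the arrays with caudal RNA in Cy5 and 0.63 on the others. Fzd7, a WNT receptor, stood at 1.01 ± 0.16 and Rspo3, a secreted enhancer of WNT signalling, at 0.99 ± 0.16. On the rostral side, Spry1, a feedback inhibitor of FGF signalling, had a ratio of -1.28 ± 0.14 and Mpped2, a phosphoesterase, -1.27 ± 0.14. Sfrp1, a secreted WNT antagonist, was measured by 2 probes at -1.08 ± 0.15 and -1.17 ± 0.19. Each of these genes had the same sign in all 5 pools, apart from the second Nr2f1 probe, which was positive in 4. Krt18, a keratin of simple epithelia, had a ratio of -1.45 ± 0.19 and the uncharacterised transcript 2310005A03Rik -1.46 ± 0.19, each from 4 pools. These means describe neither strain, as Krt18 had -0.28 in C57 and -2.61 in MF1, and 2310005A03Rik -0.37 and -2.55. The latter gene's mean was -0.90 on the arrays with caudal RNA in Cy5. Rspo3 was 0.66 on the arrays with rostral RNA in Cy5.

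None of the 11855 probes tested passed a Benjamini-Hochberg adjusted p of 0.05 in limma. The smallest adjusted p, 0.567, was shared by Spry1, Ttr, Mpped2 and Nr2f1. At an unadjusted p under 0.05 there were 367 probes, against 593 for uniform p values and 345 in simulated data with the pool shifts of these arrays and no change, 235 with a positive and 132 with a negative ratio; after centring each array on its median the split was 270 to 272. Centred pool values passed 0 probes (smallest adjusted p 0.321). The 10 arrays were also fitted singly with a dye term; the 2 arrays of a pool are not independent, so the pool was a block with a correlation of 0.333, or 0.264 when centred. Ttr alone then passed, at an adjusted p of 0.015; with centring added, 8 probes did, for Ttr, Rspo3, Sfrp1 (2 probes), Mpped2, Spry1, Esm1 and 1 unnamed transcript.

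**Figure D1:**
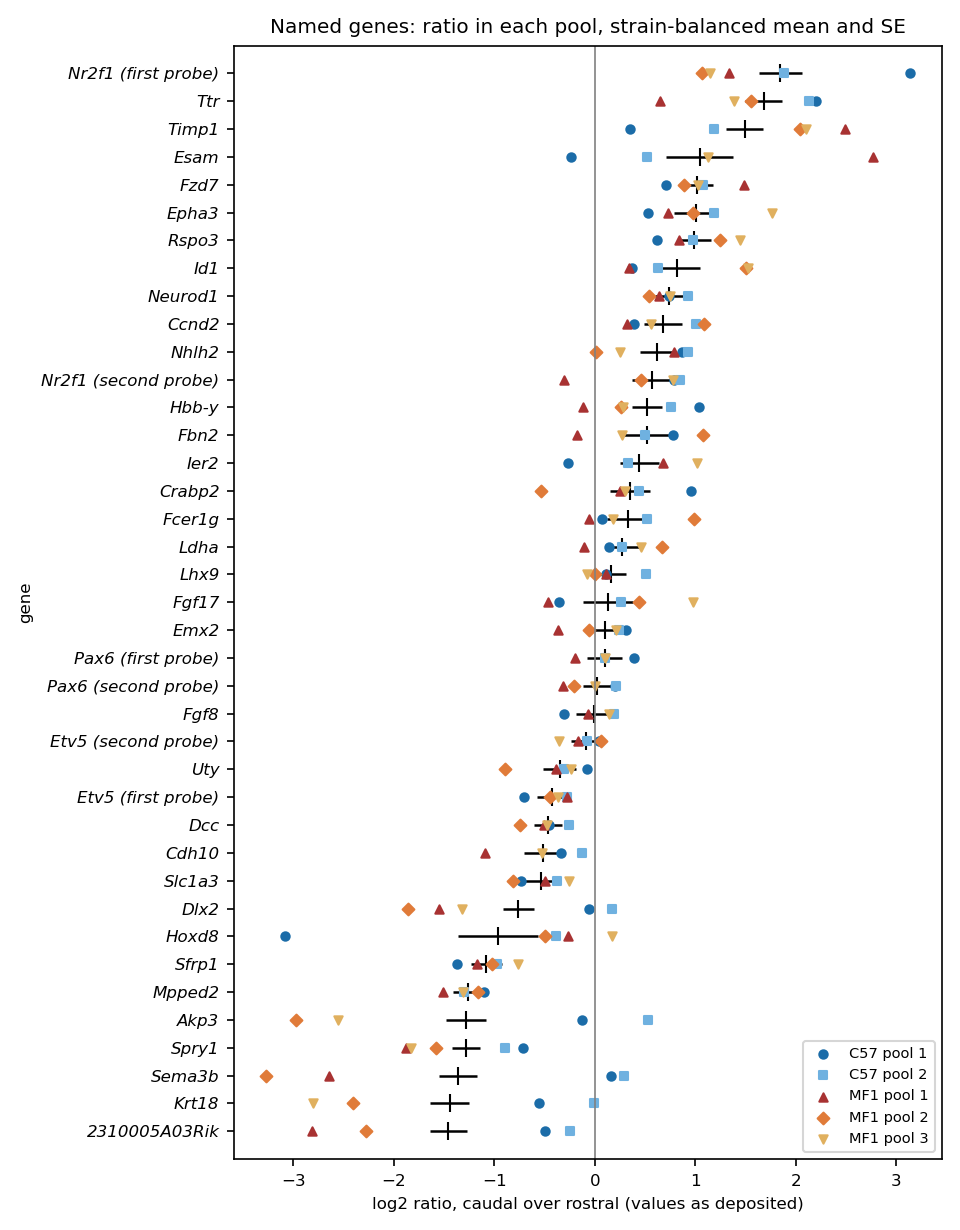
Log2 ratio of caudal over rostral RNA (x axis) for each named gene (y axis); coloured symbols are the 5 pools, and the black bar and line are the strain-balanced mean and its SE from limma. Spry1, Mpped2 and Sfrp1 lie left of 0 in all 5 pools, while Nr2f1 (first probe), Ttr, Timp1, Fzd7 and Rspo3 lie right of 0 in all 5.

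The list furthest to the rostral side by its median held genes of FGF signalling. Of 9 probes for 7 tested genes of the list of FGF ligands and feedback targets, 7 had a negative ratio and the median was -0.42. Spry1, Etv1 and Dusp6 passed when adjusted over the list alone, with ratios of -1.28 ± 0.14, -1.43 ± 0.22 and -1.07 ± 0.22; no member passed over all probes. Etv1 is a transcription factor and Dusp6 an ERK phosphatase, both induced by FGF. The ligands Fgf8 and Fgf17 themselves had ratios of -0.01 ± 0.18 and 0.13 ± 0.25, and Etv5 had -0.43 ± 0.15 and -0.09 ± 0.14 at its 2 probes. In limma's camera test with a preset correlation of 0.01 the list stood below other probes at an adjusted p of 1.4e-08; the adjusted p was 0.381 with an estimated correlation. Of its 7 tested genes, 6 were also among the gradient genes used to read the direction, so its side is not independent evidence.

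The rostral list of those gradient genes had 6 negative and 4 positive probes, a median of -0.05 and a mean of -0.35 (camera adjusted p = 1.1e-05, adjusted p = 0.381 with an estimated correlation), and Spry1, Etv1 and Dusp6 again passed adjusted over the list alone. Pax6, a transcription factor known for a rostral gradient, had ratios of 0.10 ± 0.17 and 0.02 ± 0.14 at its 2 probes. The caudal list had 6 positive and 1 negative probe and a median of 0.32 (camera adjusted p = 0.0037, adjusted p = 0.601 with an estimated correlation). Nr2f1 passed adjusted over the list alone, while Emx2, a homeobox gene known for a caudal gradient, had a ratio of 0.10 ± 0.15. Without MF1 pool 1 the camera adjusted p of the caudal list was 0.0629. Fgfr3 had too few measured ratios to be tested, and no probe was named Sp8.

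Among markers of the cortical hem and choroid plexus, the structures at the medial edge of the cortex, positive ratios were seen for 11 of 14 probes, with a median of 0.25 (camera adjusted p = 0.0037, adjusted p = 0.795 with an estimated correlation). Ttr and Rspo3 passed adjusted over the list alone, and Wnt3a, a WNT ligand of the hem, had a ratio of 0.45 ± 0.19. Without C57 pool 2 the median was 0.09 and the camera adjusted p 0.055. The WNT pathway list went both ways, with 9 negative and 9 positive probes, a median of 0.01, a mean of -0.03 and a downward camera direction (adjusted p = 0.112). Within it, Sfrp1 at both probes and Fzd7 passed adjusted over the list alone, in opposite directions. With 10 arrays fitted singly and a dye term the camera adjusted p of the WNT list was 0.0347; the adjusted p was 0.862 with an estimated correlation and pool values.

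Transcription factors linked to cortical areas had 27 positive and 4 negative probes and a median of 0.16 (camera adjusted p = 0.0197, adjusted p = 0.795 with an estimated correlation). The list median was 0.25 in C57 and 0.07 in MF1 (camera adjusted p = 8.2e-04 in C57, 0.648 in MF1 and 0.103 for the difference). Over all tested probes, which were not centred, the median was 0.13 in C57 and 0.03 in MF1. Only Nr2f1 passed adjusted over the list alone. Fezf2 had a ratio of 0.39 ± 0.16, Lhx2 0.32 ± 0.15 and Pou3f2 -0.53 ± 0.17 and 0.01 ± 0.18 at its 2 probes. The camera adjusted p was 0.209 without the 5 genes that are also gradient genes, and 0.366, 0.146 and 0.114 without MF1 pool 1, C57 pool 1 and MF1 pool 3.

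Of the lists for other tissues, blood, surface ectoderm and ventral telencephalon passed camera with the preset correlation. All 7 probes for blood genes were positive, with a median of 0.41 (camera adjusted p = 1.6e-04, adjusted p = 0.392 with an estimated correlation); the embryonic globins Hbb-y and Hbb-bh1 had ratios of 0.52 ± 0.15 and 0.51 ± 0.16, and no member passed adjusted over the list alone. The list median was 0.54 in C57 and 0.14 in MF1 (camera adjusted p = 0.299 in MF1 and 0.103 for the difference). All tested probes had medians of 0.13 and 0.03. Without C57 pool 1 or MF1 pool 1 the camera adjusted p was 0.0508 in each case. All 6 probes for surface ectoderm genes were negative, with a median of -0.34 (camera adjusted p = 5.2e-06, adjusted p = 0.381 with an estimated correlation). Krt18 and Trp63, a transcription factor of stratified epithelia at -0.80 ± 0.15, passed adjusted over the list alone. Markers of the ventral telencephalon had 7 negative and 6 positive probes and a median of -0.23 (camera adjusted p = 0.00118, adjusted p = 0.601 with an estimated correlation). The homeobox genes Dlx1 and Dlx2, at -0.99 ± 0.24 and -0.76 ± 0.15, passed adjusted over the list alone. These means describe neither strain, as Dlx1 had -0.28 in C57 and -1.69 in MF1, and Dlx2 0.06 and -1.58. The median of this list was 0.04 in C57 and -0.07 in MF1, against 0.13 and 0.03 over all tested probes. Without MF1 pool 1 its median was -0.08, its mean 0.004 and its camera adjusted p 0.165.

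**Figure D2:**
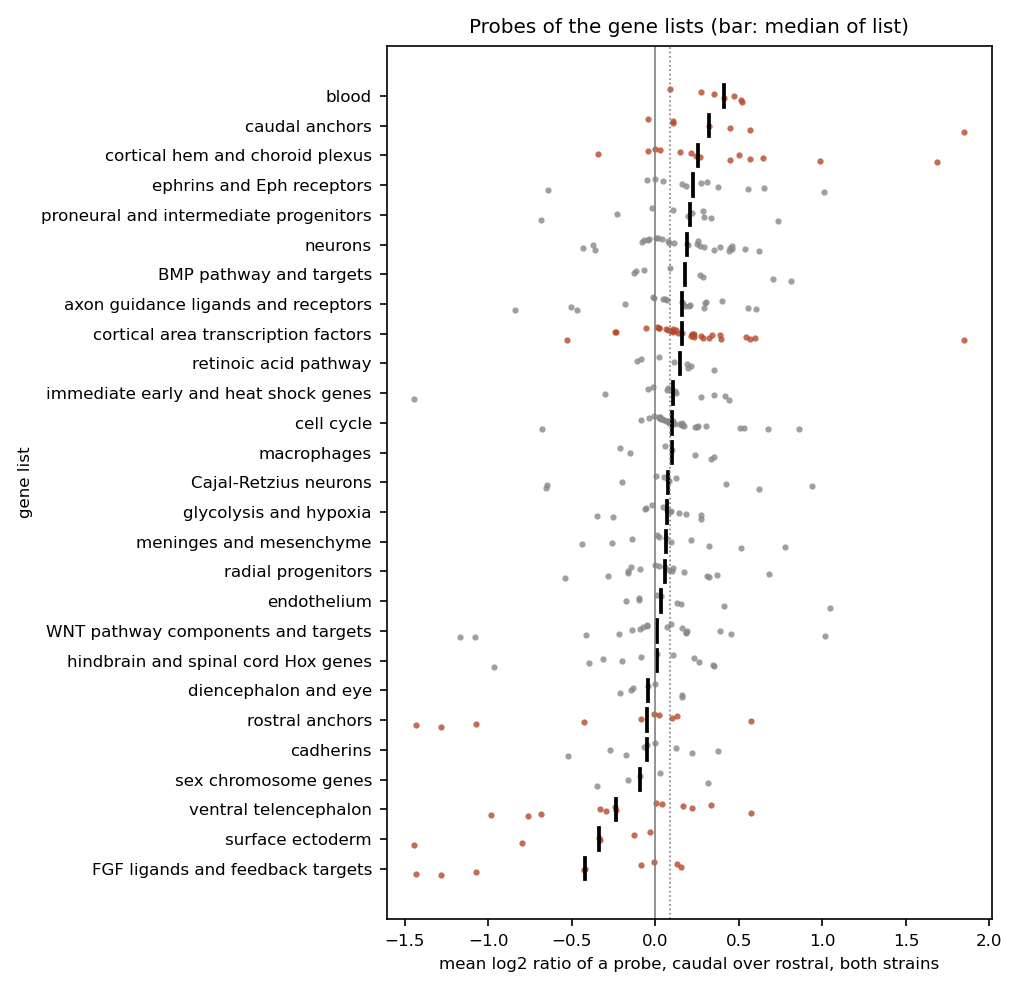
Mean log2 ratio of caudal over rostral RNA over both strains (x axis) for every tested probe of the 27 gene lists (y axis); black bars are list medians, the dotted line is the median of all probes, and coloured points belong to the 8 lists past an adjusted p of 0.05 in camera with the preset correlation. List medians run from -0.42 for FGF ligands and feedback targets to 0.41 for blood.

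Over the 27 lists, 8 passed camera with the preset correlation, 4 towards each end. The 8 include both lists of gradient genes used to read the direction. Others, such as the FGF and area lists, share genes with them, so the 8 are not separate evidence. None passed with an estimated correlation (smallest adjusted p 0.381) or in limma's fry test for a shift one way (smallest adjusted p 0.204), while 11 passed fry's test for change in either direction. The remaining 18 lists, beside WNT, had camera adjusted p from 0.112 to 0.938. Among signalling lists, the medians were 0.18 for the BMP pathway, where Id1 stood at 0.81 ± 0.23 and Id3 at 0.70 ± 0.22, 0.15 for retinoic acid with Crabp2 at 0.35 ± 0.20, 0.23 for ephrins and Eph receptors, 0.16 for axon guidance with Dcc at -0.47 ± 0.14, and -0.05 for cadherins with Cdh10 at -0.52 ± 0.19. Epha3 at 1.01 ± 0.22 and Efnb2 at -0.64 ± 0.16 passed adjusted over the Eph list alone. Axon guidance had a mean of 0.08 and a downward camera direction, and cadherins passed camera without MF1 pool 3, at an adjusted p of 0.0471 (adjusted p = 0.735 with an estimated correlation and all pools).

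For cell types of the cortex, the medians were 0.06 for radial progenitors with Slc1a3 at -0.54 ± 0.16, 0.21 for proneural and intermediate progenitors, 0.19 for neurons with Nhlh2 at 0.62 ± 0.17, and 0.08 for Cajal-Retzius neurons. Neurod1, a proneural transcription factor, stood at 0.74 ± 0.14, was positive in all 5 pools and passed adjusted over its list alone. Radial progenitors and Cajal-Retzius neurons had positive medians and means but a downward camera direction, since camera compares a list with all other probes. The cell cycle list had 28 of 32 probes positive and a median of 0.10, close to the median of all probes, 0.09; Ccnd2 stood at 0.68 ± 0.19 and 0.86 ± 0.29 at its 2 probes and Ccnd1 at -0.68 ± 0.23. Other tissues gave medians of -0.05 for the diencephalon and eye with Lhx9 at 0.16 ± 0.14, 0.01 for Hox genes, 0.06 for meninges and mesenchyme with Fbn2 at 0.52 ± 0.22, 0.03 for endothelium with Esam at 1.04 ± 0.33 from 4 pools, and 0.10 for macrophages with Fcer1g at 0.33 ± 0.21. Esam was 0.63 without MF1 pool 1 and turned to -0.05 on the arrays with rostral RNA in Cy5. The Hox list had a mean of -0.06 and a downward camera direction. Lists on the state of the tissue had medians of 0.11 for immediate early and heat shock genes with Ier2 at 0.44 ± 0.19, 0.07 for glycolysis and hypoxia (downward in camera) with Ldha at 0.27 ± 0.17, and -0.09 for sex chromosome genes with Uty at -0.35 ± 0.16.

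The next question was what each strain shows by itself. In C57, the first Nr2f1 probe had a ratio of 2.51 ± 0.34 (SE, n = 2 pools, with the spread shared by both strains) and the second 0.82 ± 0.31. Ttr stood at 2.17 ± 0.29, Mpped2 at -1.20 ± 0.22 and Spry1 at -0.81 ± 0.22. Blood markers had a median of 0.54 and FGF genes -0.34, and 10 of the 27 lists passed camera with the preset correlation; the estimated correlation was not run for single strains. No probe passed an adjusted p of 0.05 in limma (smallest adjusted p 1), and 214 had an unadjusted p under 0.05. The spread of a probe was shared by the strains without weights, though the pools were unlike. The SD across probes was 0.45 and 0.30 in the C57 pools and 0.55, 0.77 and 0.67 in the MF1 pools. The count for C57 may therefore be too low and that for MF1, below, too high. When the 2 C57 pools were fitted alone, with 1 residual degree of freedom, 51 probes passed, 27 positive and 24 negative, with Nr2f1, Ttr and Hoxd8 among them. That fit gave every probe the same variance, so a probe's own spread did not count: 7 of the 51 had opposite signs in the 2 pools. Hoxd8 had -3.08 in C57 pool 1 and -0.38 in C57 pool 2, and its mean over both strains moved from -0.97 to -0.29 without C57 pool 1.

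In MF1, Timp1 had the largest ratio of the caudal genes above, 2.21 ± 0.23 (SE, n = 3 pools). Ttr stood at 1.2 ± 0.23, and Nr2f1 at 1.19 ± 0.27 at its first probe and 0.31 ± 0.25 at its second. On the rostral side were Spry1 at -1.76 ± 0.18, Dlx2 at -1.58 ± 0.19 and Krt18 at -2.61 ± 0.27, the last from 2 MF1 pools. The median of surface ectoderm markers was -0.48, that of FGF genes -0.36 and that of hem and choroid plexus markers 0.23, and 5 lists passed camera with the preset correlation. No probe passed an adjusted p of 0.05 in limma (smallest adjusted p 0.446), and 469 had an unadjusted p under 0.05. The count changed when single pools were left out: 37 probes passed without MF1 pool 1 and 24 without MF1 pool 3. Timp1 and Sema3b were in both sets, but Sema3b had no ratio in MF1 pool 3, so leaving out that pool removed no value of it. Likewise, Krt18 and Akp3 passed without MF1 pool 1, and 2310005A03Rik without MF1 pool 3, though they had no ratio in the pool left out. Their own values therefore did not change.

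The interaction of region and strain tests whether the caudal to rostral ratio differs between MF1 and C57. The smallest p values were those of Sema3b, a secreted semaphorin, and Akp3, an alkaline phosphatase. Sema3b had ratios of -2.96 ± 0.27 in MF1 and 0.23 ± 0.27 in C57, a difference of -3.18 ± 0.38 from 4 pools. Akp3 had -2.76 ± 0.29 and 0.20 ± 0.29, a difference of -2.97 ± 0.41 from 4 pools. With incomplete pools kept, the mean ratio over both strains moved from -1.37 to -0.58 for Sema3b and from -1.28 to -0.76 for Akp3. Neither passed, as the smallest limma adjusted p over the 11855 probes was 0.999, and 223 probes had an unadjusted p under 0.05. No list passed camera for the interaction. The smallest adjusted p, 0.081, was that of proneural and intermediate progenitors and of ephrins and Eph receptors. Their medians were 0.43 and 0.11 in C57 and -0.05 and 0.44 in MF1. All tested probes had medians of 0.13 in C57 and 0.03 in MF1. The first Nr2f1 probe differed by -1.33 ± 0.43 and the second by -0.51 ± 0.40, each with a larger ratio in C57.

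**Figure D3:**
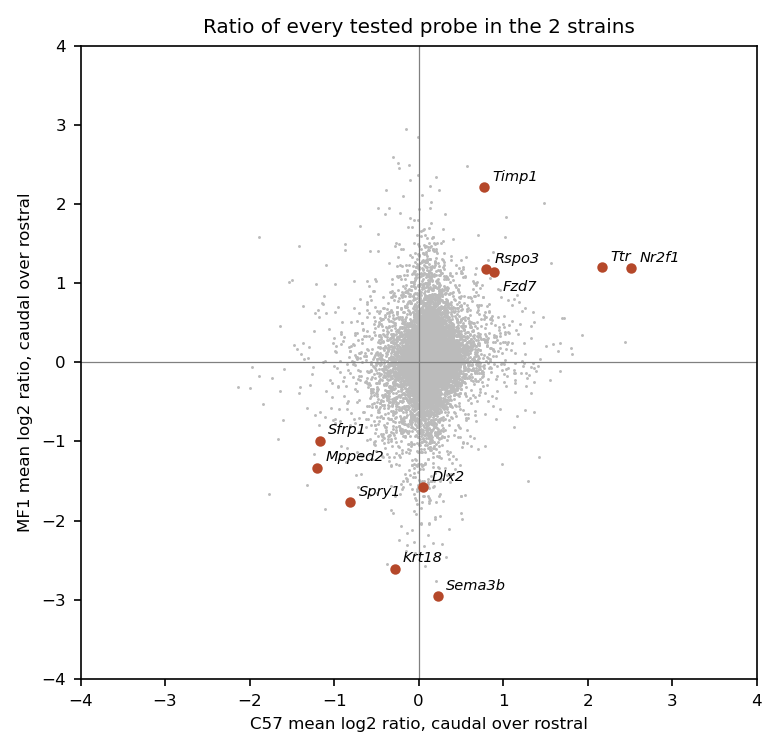
Mean log2 ratio of caudal over rostral RNA in C57 (x axis, 2 pools) against MF1 (y axis, up to 3 pools) for each of the 11855 tested probes, in grey, with 11 named genes in colour. Nr2f1 (first probe) and Ttr lie above 1 in both strains. The second Nr2f1 probe, at 0.82 in C57 and 0.31 in MF1, is not coloured. Krt18, Sema3b and Dlx2 lie below -1.5 in MF1 and between -0.3 and 0.3 in C57.

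Across probes, the mean ratios of the 2 strains had a Pearson correlation of 0.108 and a Spearman correlation of 0.105; probes are not independent replicates. With the sign of MF1 pool 3 turned the Pearson correlation was 0.0945 and the Spearman correlation 0.151, and with that of any other pool turned the latter lay between -0.0177 and 0.0177. The Spearman correlation was -0.05 between the C57 pools, -0.345 between MF1 pools 1 and 3, -0.0855 between MF1 pools 1 and 2 and 0.314 between MF1 pools 2 and 3. Between pools of different strains it ranged from -0.137 to 0.24, the highest value being that of C57 pool 1 with MF1 pool 1. For C57 pool 2 it was 0.085 with MF1 pool 2 and 0.213 with MF1 pool 3. Of 8924 probes with a ratio in all 5 pools, 436 had the same sign in each (4.89%), 371 of them positive and 65 negative; the shares of positive ratios in the pools would give 4.08% if the pools were independent. After centring it was 750 (8.40%, with 6.28% from the shares), 521 positive and 229 negative.

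The dye effect was spread more widely across probes than the tissue ratio. The half-sum of the 2 arrays of a pool, which holds the dye bias, had an SD of 0.36 across probes, against 0.27 for the ratio of caudal over rostral RNA. In limma 3162 probes had an unadjusted p under 0.05 for the dye effect and none passed an adjusted p of 0.05, which 2 probes did after centring. A dye bias shared by the 2 arrays of a pool cancels in their mean. As deposited, the 2 arrays of a pool had Spearman correlations between -0.14 and 0.127, where a strong tissue difference without dye bias would give clearly negative values, and arrays of different pools with the same dye order had Pearson correlations of up to 0.438.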

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

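Of 72 sets of 4 to 10 values examined (named genes and lists over pools, and array summaries over arrays), 2 held a value far from the others; chance alone gives about 1 in 20 such sets.

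Hoxd8, a Hox gene of the posterior body axis, had a ratio of -3.08 in C57 pool 1, while the other 4 pools lay between -0.5 and 0.17. The median of the 6 surface ectoderm probes was -1.55 in MF1 pool 3, against -0.38 to 0.09 in the other 4 pools.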

How the results depend on the processing

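All choices of alternatives were fixed before the data were examined except the ceiling values, the combined settings with centring, the lists without gradient genes, pools 1 and 2 without a block, the list settings beyond those planned and the settings of the direction count, which were chosen after seeing the data. For the mean of both strains, 0 probes passed except 1 with arrays centred and scaled, 1 with 10 arrays fitted singly and a dye term, and 8 with centring and single arrays together. For C57, 2 passed with arrays centred and scaled, 2 with centring and single arrays, and 51 with the C57 pools fitted alone; the last fit has 1 residual degree of freedom and 1 variance for all probes, and 7 of its 51 probes had opposite signs in the 2 pools. For MF1, leaving out a pool gave 0 to 37 probes, with 37 without MF1 pool 1 and 24 without MF1 pool 3. Leaving out a pool gave 0 for the other 3 contrasts, and MF1 minus C57 had 0 in every setting. A pool left alone in its strain is assumed to vary like the others. Pool numbers occur in both strains but do not pair them; with the number as a replicate block over pools 1 and 2, 0 probes passed in the mean of both strains and in MF1 minus C57, and the deviations of same-numbered pools had a correlation of 0.0656 (Pearson) over 9598 probes.

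Of the 8 lists, 0 passed with an estimated correlation and 0 with fry, and leaving out a pool left 4 to 8, with 4 without MF1 pool 1. The Pearson correlation of the strains ranged from 0.0555 to 0.129 when a pool was left out and was 0.149 on arrays with caudal RNA in Cy5. The dye effect had 2 probes past the threshold after centring, and the gradient genes on the listed side numbered 9 to 11 when a pool was left out. For single genes, 865 comparisons with an alternative kept their side of the threshold, 7 passed it newly, and Esam turned to -0.0534 on arrays with rostral RNA in Cy5. A turn of sign was counted only for genes with a main limma p under 0.05, so other genes may have turned among the 865. For single lists the numbers were 301 kept, 2 newly past and 25 lost. There a turn was counted only for lists past the threshold in either setting. The cause was not tested for any of these. Signal over background was not analysed here, so a limit from dim spots is not known.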

Other observations

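The tests on MF1 pools 1 and 3 with exchanged RNA, on the distance of 24 probes and on Dlx1 and Dlx2 were chosen only after the result was seen; the other tests were written down before.

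The cyclin genes Ccnd1 and Ccnd2 differed in sign, at -0.68 ± 0.23 and 0.68 ± 0.19 (SE, n = 5 pools). Among Eph receptors and ephrins, Epha3 at 1.01 and Epha5 at 0.65 were positive and Efnb2 at -0.64 was negative. None of these probes passed over all probes tested.

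The 5 pools can be turned in 16 ways, too few for a share under 0.05. The real labels gave 367 probes at an unadjusted p under 0.05, and 9 of the 16 gave as many; the highest other count was 2285. For lists, the real labels gave 8 and the highest other 7, so that 1 of the 16 gave as many. The count of 2285, several times the real one and the highest of 15 others, came with C57 pool 2 and MF1 pools 2 and 3 turned. These have positive median ratios and the pools numbered 1 negative ones. After centring the count was 1137, against 542 for the real labels, which points to a structure of the pools whose source was not tested. The Spearman correlation of a pool's ratios with the dye profile of the other pools had the same split of signs. It was -0.230 in C57 pool 1 and -0.143 in MF1 pool 1. In C57 pool 2, MF1 pool 2 and MF1 pool 3 it was 0.153, 0.022 and 0.139. Dye bias left over after the dye exchange was not tested as the source of this count.

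MF1 pools 1 and 3 had opposite ratios across probes, with a Spearman correlation of -0.345. A dye bias that the dye exchange did not fully cancel could add to this. The ratios had correlations of -0.143 and 0.139 with the dye profile of the other pools. After regression on that profile the correlation was -0.292 ± 0.00996 (bootstrap SD over 10697 probes, taken as independent). A value weaker than -0.1 had been set as the mark of that cause and one below -0.2 as the mark against it. The ratios followed the profile only weakly, so removing it could change little. The profile shared with the other pools thus accounted for little of the correlation, but dye bias particular to a pool was not covered. Probes with few measured arrays are argued against, since the correlation was -0.371 over the 8924 probes measured on all 10 arrays. For 20 probes picked in the other 4 pools, an exchange of rostral and caudal RNA should give a median, in the sign of those pools, of -0.81 in pool 1 and -0.64 in pool 3, going by the other pools held out alike, but it was 0.51 (SD 0.70) and 1.02 (SD 0.76), which argues against it in both; a count of signs, tried first, had left pool 1 undecided, and another form of the test was dropped because its bound was inflated by the picking. Dye bias particular to a pool, a partial mixing of the RNAs and a difference between litters or dissections remain open and were not tested.

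Probes near each other in the probe numbering had like ratios. The Spearman correlation of the mean ratio was 0.1 between direct neighbours, against at most 0.0362 in 200 shuffles. Pairs with the same gene symbol were left out. Pairs in which a probe had no single symbol were kept and may share a gene. Printing position may be a source: the correlation was 0.0858 at a distance of 12 probes and 0.0700 at 24, where the highest of the distances 17 to 23 and 25 to 31 was 0.0484, but the gap is under 2 standard errors of 0.0116. Neighbours that share a function may be another; among the 324 neighbouring pairs with no gene symbol the correlation was 0.0549 ± 0.0556, too uncertain to decide. No explanation by region or strain was tested.

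Dlx2 had ratios of -1.55, -1.86 and -1.32 in the MF1 pools and of -0.06 and 0.17 in C57, and Dlx1 had mean ratios of -1.69 and -0.28. Both genes mark the ventral telencephalon, and ventral tissue in the rostral MF1 pieces is a candidate source. It would bring other ventral genes too, yet the median MF1 minus C57 difference of the other 11 ventral probes was 0.11 (SD 0.42), at percentile 94.4 of 10000 random sets. Dlx2 differed by -1.63. Dlx5, at -0.66, and Olig1, at -0.52, went the same way, and Isl1, at 0.14, and Gsx2, at 0.11, did not. A comparison of strain means cannot show ventral tissue in single pools, which remains open. The median of all 13 ventral probes, Dlx1 and Dlx2 included, was -0.79, -0.33 and 0.25 in MF1 pools 1, 2 and 3, against -0.18, 0.13 and 0.15 over all tested probes. In C57 pools 1 and 2 it was -0.32 and 0.37, against -0.10 and 0.36. Chance among the probes tested stays open: 7 probes had an interaction p at or below that of Dlx2, where 50 simulated data sets with no change gave 23.7 on average (SD 4.73, range 14 to 36). The real count lay below every simulated set, so the simulation did not reproduce these data and cannot decide. The bounds of that test were also rewritten once its result was known. A strain difference is also open.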
